A study of Mus musculus with 8 samples.

How the data were processed

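Total RNA from lung interstitial leukocytes of WT and RagKO mice was labelled with Cy5 and a universal mouse reference RNA with Cy3 on 8 2-channel Agilent arrays, all in the same dye orientation, per the labels' protocols. The labels' protocol also describes titanium dioxide, for which no array was analysed here. The deposited table holds 1 log ratio per probe and array for 16251 probes, and its log10 base was inferred from the values, since neither the labels nor the table state it. Read as log10, the largest ratio was 737-fold over the reference, and as log2 only 7.3-fold. The T cell gene Cd8b1, with a value on 7 arrays, would differ 110-fold between WT and RagKO on a log10 scale and 4.12-fold on a log2 scale. The direction of the deposited log10 ratio, Cy5 over Cy3, was taken from the dyes in the labels. Background correction, dye normalization, spot averaging and any probe filter are not given in the sources used here. Background-level spots could therefore not be told from measured ones, and the differences of weakly expressed genes may be compressed or inflated by that correction. Column medians on the deposited scale were -0.0701 and -0.0717 for WT saline, -0.069 and -0.0725 for WT silica, -0.0521 and -0.0535 for RagKO saline and -0.0606 and -0.0571 for RagKO silica, in replicate order. They spanned 0.0677 on the log2 scale, so no further normalization was applied in the main analysis. Their centring is unknown. No 2 columns held identical values.

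Values were multiplied by 3.3219 to give log2 ratios. Of the probes, 14716 had a value on all 8 arrays and were used, and 1535 were missing on up to 4 arrays. The platform's gene table gave 1 gene symbol for 14488 probes, several for 10 and none for 1753. For 14460 probes the Entrez identifier was found in the gene table of assembly GRCm38.p6, which changed 0 symbols. Probes with several or no symbols were left out of gene counts, and the probes of a gene were averaged, which left 11597 genes, 1478 of them with more than 1 probe. Where the probes of a named gene disagreed on passing the test (Itgam in WT, Vegfa and Tmem100 and Dnajb4 in the difference, Rpl11 in WT, Lef1 in RagKO and the difference, Bcl2 in RagKO, Ighm in the difference), the average was kept.

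Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment and a threshold of 0.05. Comparisons of a pair of groups and the interaction used a model of 4 group means over all 8 arrays, with 4 residual degrees of freedom. The effects averaged over the other factor used an additive fit of genotype and exposure, with 5. The median SE per gene was 0.13 on the log2 scale for a pair of groups and 0.18 for the interaction. Differences are silica minus saline, RagKO minus WT, or the RagKO silica effect minus the WT silica effect. Gene lists of cell types and pathways, 43 in all, were fixed before the data were examined, as were the tests of the comparisons and the alternatives. Tests of exchanged arrays, of sex and of the share of leukocytes were chosen later. The 41 lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists. With an estimated correlation camera uses the 4 residual degrees of freedom, and with the preset one a number near that of all genes. A call lost with an estimated correlation therefore need not come from correlation between genes. Fry asks whether a list's genes move on balance in 1 direction and does not compare them with other genes. Named genes were the 8 largest rises and 8 largest falls among genes past the threshold whose arrays did not overlap between the groups (overlap was not considered for the interaction), up to 4 members of each called list and up to 2 of a list not called, by smallest p, and 16 genes fixed in advance, of which 1 is not reported here. RIKEN, predicted and LOC genes would have been passed over, and 0 were. Chosen after their values were seen were Xist, Eif2s3y, Kdm5d, Rn28s1, Cd8b1 and Iftap.

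Both fits and the list test were tested on simulated data for the same 11597 genes. For silica in WT, 76% of genes changed by 1 on the log2 scale and 98% of those changed by 2 were recovered, and 6.1% of calls were false. For silica in RagKO these were 94%, 100% and 5.8%, and for the difference between the silica effects 54%, 94% and 3.1%. For the averaged silica effect they were 86%, 96% and 8%. Only 50 genes were changed at each size, far fewer than were called in the real data. The adjusted threshold depends on how many genes change, so these rates need not hold there. A list moved by 1 was called in each of 5 simulated comparisons, each drawn once, with 0 unmoved lists called when the protease list was left out. The simulated noise was independent between genes. The simulation therefore does not show how often lists of correlated genes are falsely called. Alternatives were median centring, quantile normalization, rows with up to 2 missing arrays, a filter on weakly varying genes, single probes, the probe with the highest mean, robust eBayes, array weights, the compared groups alone, a replicate block, thresholds of 0.01 and 0.10, a contrast of group means in place of the additive fit, and leaving out each array. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9. No coordinates are given, because no genome build is named for the probes.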

Results

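Gene expression was measured in lung interstitial leukocytes, the white blood cells released from digested lung tissue and collected on a Percoll density gradient, on 8 microarrays in 4 groups of 2. Wild-type (WT) C57Bl/6 mice and Rag1-deficient mice, which make no mature T or B cells, received either saline or crystalline silica through the nose once a week for 4 weeks, with 1 mg of silica in 25 µl per dose. The Rag1-deficient mice were also given 300 µg of an antibody against NK1.1 per injection to remove natural killer (NK) cells, and are called RagKO here, so that the missing gene and the NK depletion could not be separated. The study's title sets the response to silica in WT mice against that in RagKO mice. Each array compared leukocyte RNA with a universal mouse reference RNA, and between 15661 and 16119 of 16251 probes had a value. All differences below are on a log2 scale that rests on reading the deposited ratios as log10, a base inferred from the values. Read as log2, each log2 difference would be smaller by the factor 3.3219, with no effect on the tests. The pair of arrays within a group correlated across probes with r between 0.9778 and 0.9901, and the lowest r between any 2 arrays was 0.6769. The labels call the arrays of a group biological replicates without saying how many mice each holds, so p-values measure only the spread between these arrays. Having 2 arrays per group limits the precision of every value. Of the genes fixed in advance, Rag1, Rag2, Ncr1 and Nos2 were not analysed here because no probe carried those symbols, so the deleted gene itself gives no check of the labels.

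The first comparison asked how RagKO leukocytes differed from WT leukocytes after saline alone, and the largest differences were losses of lymphocyte transcripts. On the same arrays a 28S ribosomal RNA probe (Rn28s1) read 3.67 and 3.71 in WT and 2.43 and 2.08 in RagKO, and the X-inactivation transcript Xist -0.24 and -0.21 against -2.47 and -2.64 (0.17 and -0.15 against -0.71 and -0.81 on its other probe). The Y-linked Eif2s3y read 2.32 and 2.27 in WT against 2.90 and 2.60 in RagKO, while Kdm5d, also Y-linked, went the other way (0.56 and 0.42 against -0.43 and -0.19). All 9 measured B cell markers and all 11 T cell markers were lower in RagKO, as were 9 of 12 plasma cell and immunoglobulin genes (10 when adjusted over the list alone) and 14 of 15 NK cell markers. Ms4a1, which encodes the B cell surface protein CD20, was 104-fold lower (log2 difference -6.70, SE 0.11, adjusted p = 1.05e-10), with a log2 ratio of 4.57 ± 0.09 in WT and -2.13 ± 0.01 in RagKO (SD, n = 2). The immunoglobulin light chain gene Iglv1 was lower by a log2 difference of -7.70, the antibody-joining Jchain by -5.88, and the B cell coactivator Pou2af1 by -5.70. Ly6d (-5.60), the BAFF receptor Tnfrsf13c (-5.17) and the variable segments Igkv4-57-1 (-6.16) and Ighv1-17 (-4.94) completed the 8 largest falls; immunoglobulin segments share sequence, so their individual values are uncertain. Among T cell genes, Cd5 was lower by -3.95, Cd6 by -3.67 and Cd8a by -2.95, and among NK and cytotoxic genes Ctsw was lower by -3.08 and Il2rb by -2.77. Over the whole NK cell list the median was only -0.89, against -1.71 for T cell and -2.53 for B cell markers. Ighm was lower by -4.45. Cd3e, missing on 1 array, lay between -0.32 and 0.14 on every other array and was not tested.

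Antigen-presenting and stimulus-response genes were also lower in RagKO after saline. The leukocytes were measured mixed and RagKO mice lack mature T and B cells. Loss of those cells could therefore not be told from a change in other cells. Of 14 MHC class II and antigen presentation genes 10 were lower (11 when adjusted over the list alone) and 2 higher, led by H2-Oa (-3.88), the class II transactivator Ciita (-3.21), Cd74 (-2.02) and H2-Ab1 (-1.91). Of 24 immediate early genes 17 were lower and 3 higher (Dusp2 -4.21, Junb -2.58). Of 28 cell cycle genes 18 were lower and 2 higher, Pcna by 1.65. Of 16 neutrophil markers 12 were lower and 2 higher, with the chitinase-like Chil3 at -1.77 and Ltf at 1.64. Of 15 conventional dendritic cell markers 8 were lower and 3 higher (Ccr7 -2.58). Of 9 group 2 innate lymphoid cell genes 6 were lower (Icos -3.73, which is also among the T cell markers). Of 20 interferon-gamma response genes 12 were lower and 4 higher (Irf8 -2.06). For the lists in this paragraph the counts adjusted over the list alone were the same except where given. The macrophage scavenger receptor Marco was lower by -2.47 and Arg1, an arginine-degrading enzyme, by -2.21, whereas Msr1 was higher by 1.37 and Tnf by 0.50. Col1a1 (-1.16), Ifng (-0.80) and Il1b (-0.70) were lower, and Nlrp3 (0.01) and Tgfb1 (-0.19) did not pass the test.

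Genes of lung structural cells were higher in RagKO after saline, but not those of every type. Of 21 lung epithelium markers 15 were higher and 2 lower (Cdh1 2.87, Slc34a2 2.80, Cldn18 2.44, Krt18 2.22). Of 18 fibroblast and smooth muscle markers 13 were higher and 4 lower (Tagln 3.12, Myh11 3.02, Mgp 2.30, Inmt 2.19). Of 18 endothelial markers 6 were higher and 9 lower, with a median of -0.32 and no list call (adjusted p = 0.332; Emcn 2.30, Eng -1.34). Oxidative stress genes (14 of 24 higher, 2 lower; Gsta1 2.70, Cat 2.32) and heat shock genes (11 of 15 higher, 2 lower; Dnaja1 2.38, Hsp90aa1 1.86) were also higher. For these 5 lists the counts adjusted over the list alone were identical. The 8 largest rises were those of the aminopeptidase gene Enpep (4.34), Gsta3 (3.70), the integrin gene Itga8 (3.59), Aspn (3.58), Ldhb (3.57), the cytokine gene Il33 (3.39), Dram1 (3.37) and Dync2li1 (3.37). In total 7680 of 11597 genes differed, 4292 higher and 3388 lower in RagKO (limma, adjusted p below 0.05), of which 2686 differed at least 2-fold. After median centring 3888 were higher and 3771 lower, so most of the excess of higher genes rests on the normalization. Of 41 lists tested with limma's camera, 15 shifted, 4 up and 11 down, with adjusted p from 7.44e-07 to 0.044. None of these calls held with an estimated correlation, where camera also has only 4 degrees of freedom. Of the lists, 2 had an unadjusted p below 0.05 in that test, and fry called 30. B cell markers, with an estimated correlation of -0.02, went from an unadjusted camera p of 1.81e-08 to 0.00425. Correlation therefore did not by itself undo that call. The adjusted p with an estimated correlation was 0.159 for B and T cell markers, 0.564 for plasma cell genes, 0.473 for group 2 innate lymphoid cell, oxidative stress and heat shock genes, 0.705 for epithelium and fibroblast markers, 0.717 for interferon-gamma response genes and 0.587 for the other 6.

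**Figure D1:**
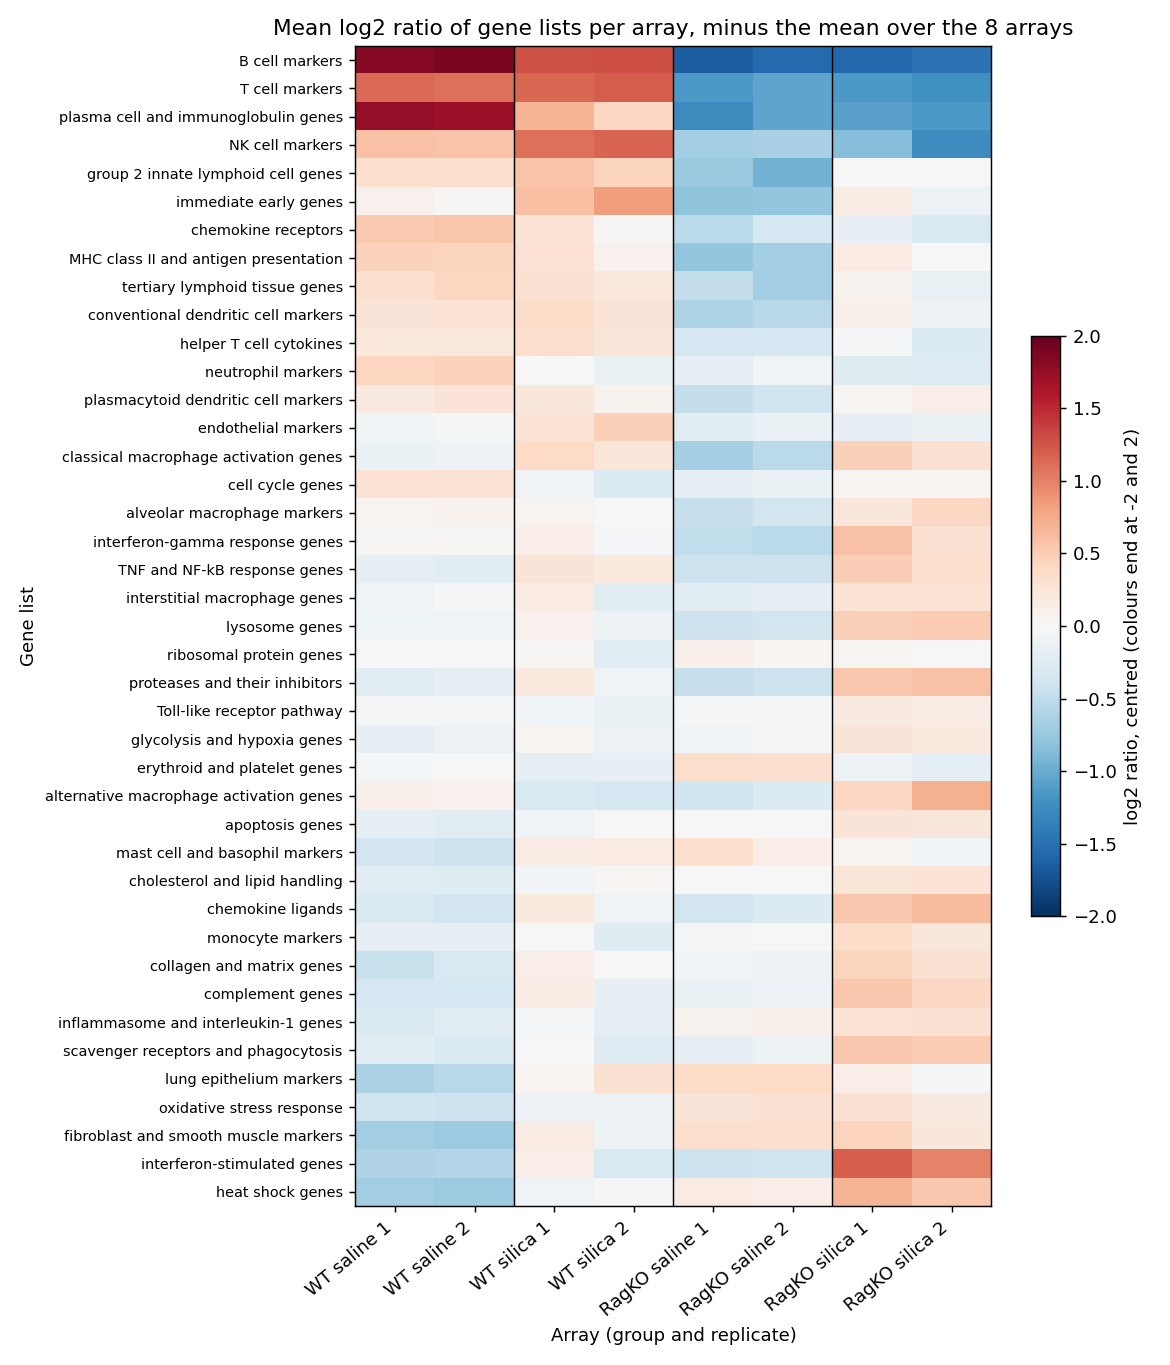
Mean log2 ratio of each of 41 gene lists (rows) on each of the 8 arrays (columns, by group and replicate), minus the list's mean over the 8 arrays; red is higher and blue lower. Lists are ordered by the difference between RagKO and WT arrays, from the B cell, T cell, plasma cell and NK cell lists, lower in RagKO, to interferon-stimulated and heat shock genes.

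After silica, lymphocyte genes were again lower in RagKO than in WT, and interferon-stimulated and alternative macrophage activation genes were higher. The 28S probe (Rn28s1) read 2.17 and 2.45 in WT and 0.86 and 0.59 in RagKO on these arrays, and sex-linked transcripts differed within RagKO, with Eif2s3y at 0.34 and 1.05 in WT against 2.42 and -2.22, Kdm5d at -0.56 and -0.15 against -0.22 and -1.02, and Xist at 0.82 and 0.48 against -2.71 and 2.22 (0.25 and -0.02 against -1.03 and 1.52 on its other probe). RagKO leukocytes had less of all 11 T cell markers, 8 of 9 B cell markers, 14 of 15 NK cell markers and 8 of 12 plasma cell genes (1 was higher) than WT leukocytes, with the same counts adjusted over the list alone. The largest falls were in Ms4a1 (-6.36), Iglv1 (-6.16), Pou2af1 (-5.17), Ly6d (-4.84), Igkv4-57-1 (-4.66), Cd5 (-4.35), Tnfrsf13c (-4.20) and the lymphocyte transcription factor gene Ets1 (-4.18). Of 26 interferon-stimulated genes 22 were higher and 1 lower (Usp18 2.63, Ifit2 2.62, Isg15 2.47, Ifitm3 1.65). Of 21 alternative macrophage activation genes 14 were higher and 2 lower (Arg1 3.51, Clec7a 1.88, Chil4 1.19). Lysosome genes (14 of 25 higher, 1 lower; Cd63 1.80, Ctsl 1.71) and heat shock genes (10 of 15 higher; Dnaja1 1.89) were higher. Immediate early genes (15 of 24 lower, 3 higher; Dusp2 -3.19, Egr1 -1.91) and endothelial markers (12 of 18 lower, 2 higher, or 3 higher when adjusted over the list alone; Sox18 -1.80, Eng -1.54) were lower. For the other 5 lists the counts adjusted over the list alone were identical. The largest rises were in the gluconeogenesis enzyme gene Fbp1 (3.62, SE 0.36, adjusted p = 1.98e-05), Arg1 (3.51), Lrmda (3.46), Ifi207 (3.44), Atp5l (3.35), Stard3nl (3.02), the acute-phase gene Saa3 (2.99) and Pnp (2.95). Msr1 was higher by 2.52, Tnf by 0.92 and Nlrp3 by 0.47. Marco was lower by -0.69, Ighm by -3.41, Ifng by -1.87, Col1a1 by -1.11 and Il1b by -0.42, and Tgfb1 (0.11) did not pass.

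In this comparison 6970 genes differed, 3913 higher and 3057 lower. After median centring 3507 were higher and 3366 lower. Camera called 10 lists, 4 up and 6 down, with adjusted p from 8.29e-09 to 0.0435; after quantile normalization it called 16, of which 11 were up and 5 down. None was called with an estimated correlation (2 at an unadjusted p below 0.05, and 30 by fry), where the adjusted p was 0.111 for T and B cell markers, 0.605 for NK cell markers and heat shock genes, and 0.804 for the other 6. The genotype differences after saline and after silica correlated across genes with r = 0.7686, and 95.3% of the 5602 genes that passed in both had the same direction; genes are not independent replicates. With both exposures in an additive fit, 7353 genes differed between the genotypes, 4171 higher and 3182 lower in RagKO. After median centring 3765 were higher and 3615 lower in that fit.

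The next comparison asked how silica changed leukocyte expression in WT mice. No measured gene checks which WT arrays had silica, so WT directions rest on the labels. Chemokine, immediate early and stress genes rose. Of 26 chemokine ligands 15 rose and 3 fell (17 and 4 when adjusted over the list alone). The neutrophil-attracting Cxcl1 was up 4.65-fold (log2 difference 2.22, SE 0.19, adjusted p = 0.00011), from -0.87 ± 0.13 to 1.35 ± 0.19 (SD, n = 2). Cxcl3 rose by 1.72, while Ccl8 fell by 2.91 and Cxcl13 by 1.71. Of 24 immediate early genes 12 rose (16 over the list alone), led by Egr1 (2.18), Jun (1.22), Fosb (1.15) and Atf3 (0.98). Of 15 heat shock genes 10 rose (14 over the list alone; Hsph1 1.22, Dnajb1 1.20). Of 21 TNF and NF-kB response genes 8 rose (10 rose and 1 fell over the list alone; Tnfaip3 1.65, Nfkbiz 0.73). Of 26 interferon-stimulated genes 10 rose and 1 fell (16 and 1 over the list alone; Cxcl10 1.62, Ifit1 1.36, Ifit3 1.31). NK cell markers rose in 8 of 15 cases (12 over the list alone; Klra8 1.12, Gzma 0.97, Fasl 0.84); Klra genes share sequence, so Klra8 is uncertain. T cell markers showed no shift, with 1 of 11 up and 1 down (Icos 0.97, Thy1 -0.45; adjusted p = 0.968), a median of -0.0025 and a mean of 0.06, so median and mean differed in sign. The adjusted p with an estimated correlation was 0.313 for chemokine ligands, 0.28 for immediate early genes, 0.174 for heat shock genes, 0.273 for TNF response genes, 0.476 for interferon-stimulated genes and 0.359 for NK cell markers.

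Antibody, B cell and proliferation genes fell after silica in WT mice. Plasma cell and immunoglobulin genes fell in 9 of 12 cases (9 over the list alone; Derl3 -3.24, Jchain -3.23, Mzb1 -1.81, Iglv1 -1.65) and B cell markers in 6 of 9 (6 over the list alone; Tnfrsf13c -1.16, Ms4a1 -0.96). Cell cycle genes fell in 16 of 28 cases (23 fell and 2 rose over the list alone), led by Mki67 (-1.44) and Top2a (-0.96). Of 16 neutrophil markers 8 fell and 2 rose (the same over the list alone), with Chil3 at -2.20, Stfa2l1 at -1.72 and Ltf at 1.37. Of 14 MHC class II genes 5 fell and 1 rose (7 and 1 over the list alone; Ciita -1.12, H2-Oa -0.98). Of 9 chemokine receptors 2 fell (4 over the list alone; Ccr6 -1.58). For plasma cell and cell cycle genes the adjusted p with an estimated correlation was 0.273; it was 0.212 for B cell markers, 0.314 for neutrophil markers and 0.476 for MHC class II genes and chemokine receptors. Of 21 alternative macrophage activation genes 9 fell and 4 rose (11 and 5 over the list alone) without a list call (adjusted p = 0.0612), with Chil4 at -1.52 and Socs3, of the classical activation list, at 1.09. Arg1 fell 5.91-fold (-2.56, SE 0.32, adjusted p = 0.000681).

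Lung structural genes rose together after silica in WT mice. Epithelium markers rose in 14 of 21 cases and fell in 1 (15 and 1 over the list alone; Slc34a2 1.73, Nkx2-1 1.73, Cdh1 1.38, Krt18 1.12). Fibroblast and smooth muscle markers rose in 14 of 18 (17 over the list alone; Gsn 1.44, Mgp 1.29, Myh11 1.20). Endothelial markers rose in 10 of 18 with 1 fall (12 and 1 over the list alone; Vwf 1.11, Esam 0.94). The medians of these 3 lists were 0.92, 0.69 and 0.52. Collagen and matrix genes rose in 13 of 27 cases and fell in 1 (14 and 1 over the list alone, with Timp3 at 1.25 and Ccn2 at 1.18). Genes of the mast cell and basophil list rose in 5 of 7 cases (6 over the list alone, with Kit at 0.65). That list also holds the cytokine gene Il6 (1.22), so the list's rise need not come from mast cells or basophils. Smaller shifts upward were called for oxidative stress (9 of 24 rose; Gclc 1.19), classical macrophage activation (5 of 12 rose, 2 fell), complement (7 of 16 rose, 1 fell; C4b 1.33), proteases and their inhibitors (8 of 23 rose, or 9 over the list alone, 2 fell; Slpi -1.96, Mmp3 1.24) and lipid handling (5 of 22 rose, or 7 over the list alone, 1 fell; Apoc1 1.14). Epithelium markers had an adjusted p of 0.28 with an estimated correlation; it was 0.273 for fibroblast, endothelial, mast cell, oxidative stress and lipid genes, 0.359 for collagen genes, 0.4 for classical activation genes and 0.476 for complement and protease genes.

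Across all genes, silica changed 2283 in WT mice, 1331 up and 952 down, of which 271 rose and 89 fell at least 2-fold. Camera called 22 lists, 16 up and 6 down (adjusted p from 1.87e-08 to 0.0269), and none with an estimated correlation (3 at an unadjusted p below 0.05). Fry called 19, of which 17 were also called by camera. The 8 largest rises were those of Cfap65 (2.36), Cxcl1, Egr1, the retinoic acid-degrading Cyp26b1 (2.12), Mal2 (2.05), the noradrenaline transporter gene Slc6a2 (2.02), Myh7 (1.97) and Vnn1 (1.94). The 8 largest falls were those of Oosp1 (-3.89), Fbp1 (-3.49), the eosinophil chemokine gene Ccl24 (-3.49), Derl3, Jchain, and the immunoglobulin segments Igkv8-19 (-3.08), Ighv1-77 (-3.04) and Igkv6-20 (-3.01). Tnf rose by 0.67, Ifng by 0.93, Col1a1 by 0.79 and Marco by 0.51, Ighm (-1.02) and Il1b (-0.39) fell, and Msr1 (0.11), Nlrp3 (-0.07) and Tgfb1 (0.04) did not pass. On the same arrays Eif2s3y read 2.32 and 2.27 after saline and 0.34 and 1.05 after silica, and Kdm5d 0.56 and 0.42 against -0.56 and -0.15. A probe for Xist read -0.24 and -0.21 against 0.82 and 0.48, whereas the ranges overlapped on the other Xist probe (0.17 and -0.15 against 0.25 and -0.02). The 28S probe (Rn28s1) read 3.67 and 3.71 against 2.17 and 2.45. The count fell to 940 without WT saline replicate 1, to 861 without WT saline replicate 2, and to 1130 without WT silica replicate 2. At an adjusted p below 0.01 it was 1021.

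**Figure D2:**
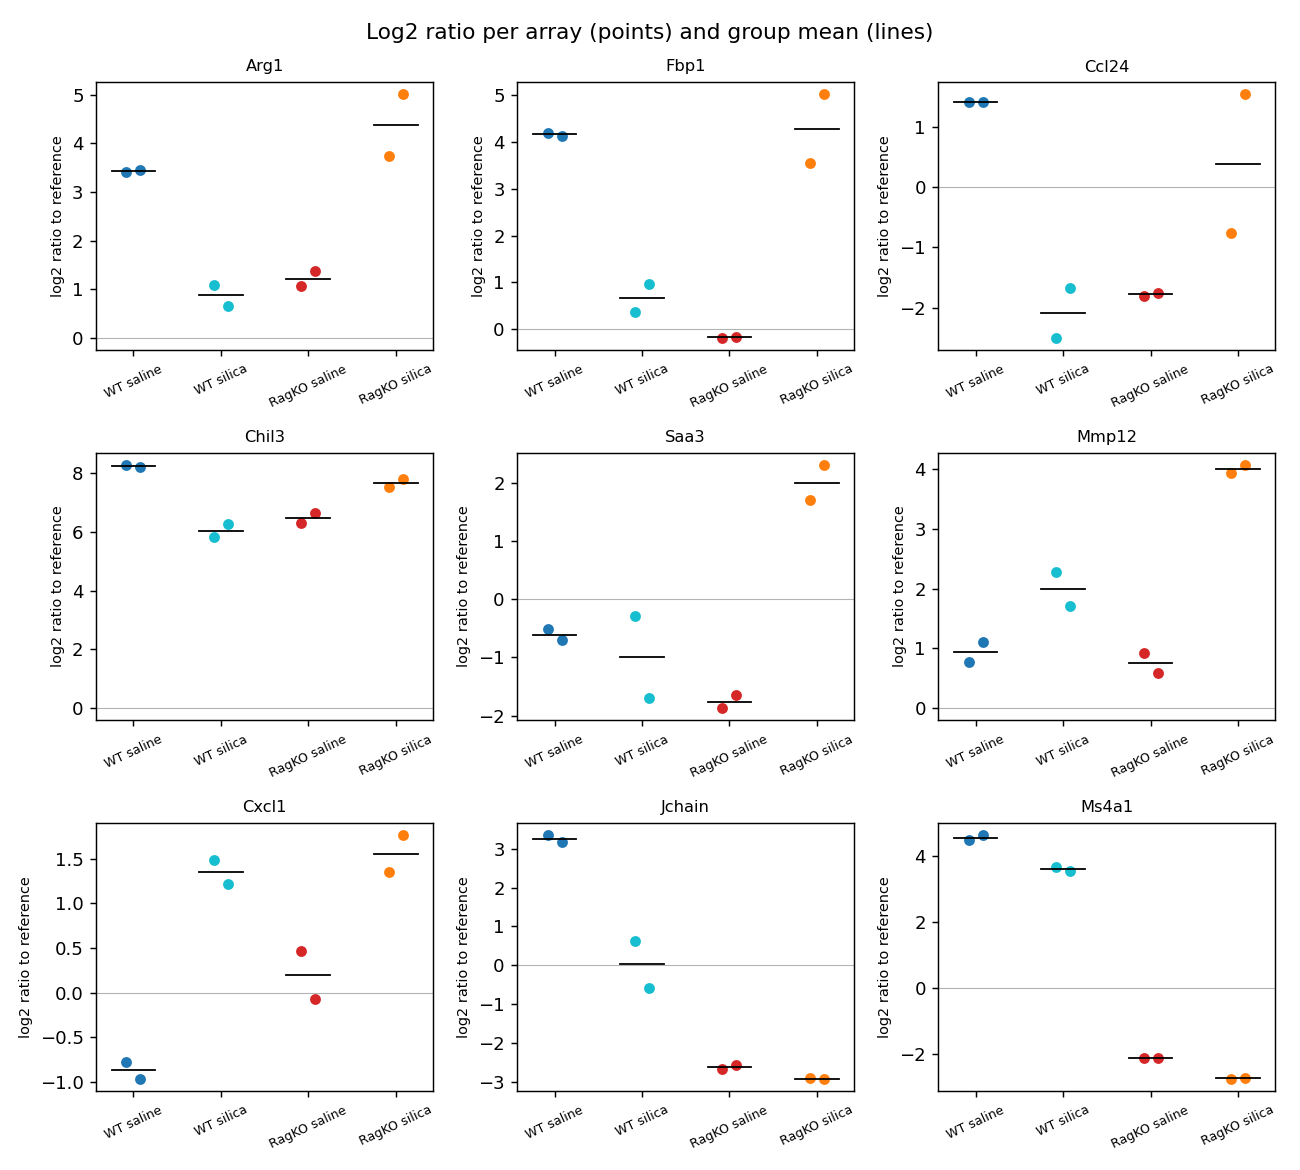
Log2 ratio to the reference RNA (vertical axis) of 9 genes in the 4 groups; each point is an array and each line the mean of 2 arrays. Arg1, Fbp1, Ccl24 and Chil3 were lower after silica in WT and higher after silica in RagKO. The 2 RagKO silica arrays lay apart for Ccl24 (-0.75 and 1.53), Fbp1 (3.56 and 5.02) and Arg1 (3.75 and 5.01), with replicate 2, the array with high Xist, the higher.

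In RagKO mice interferon, lysosome, protease and macrophage genes rose after silica. Interferon-stimulated genes rose in 24 of 26 cases (24 over the list alone), with a median of 1.80 (Ifit1 2.59, Cxcl10 2.32, Zbp1 2.17, Usp18 1.75). Interferon-gamma response genes rose in 18 of 20 (18 over the list alone; Irgm1 1.53, Iigp1 1.22, Gbp6 1.11), although Ifng itself did not pass (-0.15). Lysosome genes rose in 19 of 25 cases (20 over the list alone; Ctsk 2.69, Lgmn 1.94, Acp5 1.69). Proteases and their inhibitors rose in 17 of 23 with 2 falls (19 and 2 over the list alone). Mmp12, the macrophage elastase, rose 9.51-fold (3.25, SE 0.19, adjusted p = 1.26e-05), and the urokinase gene Plau rose by 1.61. Of 21 alternative macrophage activation genes 15 rose and 1 fell (15 and 2 over the list alone; Arg1 3.16, Egr2 1.83, Il4ra 1.66, Chil4 1.23). Of 12 classical activation genes 9 rose and 1 fell (the same over the list alone; Irf5 1.73, Socs3 1.57). Scavenger receptor and phagocytosis genes rose in 13 of 25 cases and fell in 1 (the same over the list alone), with Marco up by 2.28, Lgals3 by 2.00 and Msr1 by 1.26. Alveolar macrophage markers rose in 13 of 20 cases and fell in 2 (13 and 3 over the list alone; Car4 2.52, Abcg1 1.23). MHC class II genes rose in 11 of 14 (11 over the list alone; Ctss 2.00, Ifi30 1.27, H2-Ab1 0.99). With an estimated correlation the adjusted p was 0.198 for each of these 9 lists.

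Inflammatory signalling genes rose in RagKO as well. Chemokine ligands rose in 17 of 26 cases and fell in 1 (19 and 3 over the list alone; Ccl7 2.79, Cxcl5 2.57, Ccl2 2.13). TNF and NF-kB response genes rose in 17 of 21 (19 over the list alone; Nfkbie 1.49, Icam1 0.87). Immediate early genes rose in 17 of 24 (17 over the list alone; Fosb 1.25, Dusp1 1.22) and heat shock genes in 8 of 15 (10 rose and 1 fell over the list alone; Bag3 1.13, Hspa1b 1.07). Group 2 innate lymphoid cell genes rose in 6 of 9 cases (7 over the list alone; Ptgir 1.68), and conventional dendritic cell markers in 10 of 15 with 1 fall (11 and 1 over the list alone; Relb 1.34, Ccr7 1.13). Complement genes rose in 10 of 16 with 3 falls (11 and 3 over the list alone; C1qb 1.64, C4b 1.57) and collagen and matrix genes in 14 of 27 with 2 falls (14 and 3 over the list alone; Col3a1 1.89, Timp2 1.37, Eln 1.04). Lists with smaller upward shifts were cell cycle (6 of 28 rose, 1 fell; Birc5 0.81, Mki67 0.64), interstitial macrophage (8 of 17 rose, 2 fell, or 3 over the list alone; Ms4a7 1.89), tertiary lymphoid tissue (4 of 10 rose, and 1 fell over the list alone), glycolysis and hypoxia (8 of 22 rose, 2 fell; Hk2 0.87) and apoptosis genes (5 of 18 rose; Casp8 1.09). Erythroid and platelet genes fell in 5 of 11 cases (8 over the list alone; Tfrc -1.15). Lung epithelium markers fell in 8 of 21 (9 fell and 1 rose over the list alone; Scgb3a1 -1.25, Scgb1a1 -0.97, Krt18 -0.60) and NK cell markers in 8 of 15 with 1 rise (the same over the list alone; Klrc1 -1.17, Klrd1 -0.65). The adjusted p with an estimated correlation was 0.371 for collagen, 0.309 for complement, 0.437 for interstitial macrophage, 0.278 for tertiary lymphoid and 0.43 for epithelium genes, 0.463 for cell cycle, NK cell and glycolysis genes, and 0.198 for the remaining 8 lists of this paragraph.

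Across all genes, silica changed 3795 in RagKO mice, 1950 up and 1845 down, of which 360 rose and 155 fell at least 2-fold. Camera called 25 lists, 22 up and 3 down (adjusted p from 2.69e-16 to 0.0245), and none with an estimated correlation (8 at an unadjusted p below 0.05). Fry called 28, of which 23 were also called by camera. Fbp1 rose most (4.47, SE 0.36, adjusted p = 4.48e-05), followed by Saa3 (3.76), Mmp12, the anion exchanger gene Slc26a4 (3.21), Arg1, the goblet cell gene Clca1 (3.08), the activin subunit gene Inhba (2.91) and the monocyte chemokine gene Ccl7. The largest falls were in Pon1 (-2.32), Myl7 (-2.28), Cyp2a5 (-2.06), the oxidant-defence genes Gsta3 (-2.07), Gpx2 (-1.91) and Nqo1 (-1.82), Esm1 (-1.85) and Bex2 (-1.84). Tnf rose by 1.09, Col1a1 by 0.84, Nlrp3 by 0.39 and Tgfb1 by 0.34, and Il1b (-0.11) and Ighm (0.02) did not pass. RagKO silica replicate 2 differed in sex-linked transcripts from the other RagKO arrays, with Xist at 2.22 against -2.71 to -2.47 (1.52 against -1.03 to -0.71 on the other probe), Eif2s3y at -2.22 against 2.42 to 2.90 and Kdm5d at -1.02 against -0.43 to -0.19, and the 28S probe read 2.43 and 2.08 after saline and 0.86 and 0.59 after silica. The count fell to 2380 without RagKO saline replicate 1 and to 2393 without RagKO silica replicate 1, and at an adjusted p below 0.01 it was 1974.

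Whether the response to silica differed between the genotypes was tested directly as an interaction. It did for 2697 genes, with 1274 responding more positively and 1423 more negatively in RagKO than in WT. The 8 largest positive differences were in Fbp1 (7.96, SE 0.52, adjusted p = 4.42e-05), Arg1 (5.72), Ccl24 (5.65), Clca1 (4.23), Saa3 (4.14), Ccl8 (3.57), Oosp1 (3.44) and Chil3 (3.39). Arg1 went from 3.43 ± 0.03 to 0.87 ± 0.30 with silica in WT and from 1.22 ± 0.23 to 4.38 ± 0.89 in RagKO (log2 ratio, SD, n = 2). The 8 largest negative differences were in Cyp2a5 (-3.80), Mal2 (-3.05), the monoamine oxidase gene Maob (-2.98), Pon1 (-2.94), Bex2 (-2.87), Cytl1 (-2.84), Esm1 (-2.78) and Gpx2 (-2.70). Marco (1.77), Msr1 (1.15) and Ighm (1.04) responded more positively in RagKO and Ifng (-1.08) more negatively, whereas Col1a1 (0.05), Il1b (0.28), Tnf (0.42), Nlrp3 (0.46) and Tgfb1 (0.30) did not pass. The 2 Ighm probes disagreed, with 1 past the test. Neither Ighm probe passed for silica in RagKO (-0.03 and 0.07), so the Ighm difference came from WT. These differences take the WT labels as given: with the WT saline and WT silica arrays exchanged, a test chosen after the results were seen, Fbp1 (0.97) and Arg1 (0.60) would not pass, and 3559 genes would. The count fell to 1649 without WT saline replicate 1 and to 1647 without WT saline replicate 2, and at an adjusted p below 0.01 it was 1359.

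**Figure D3:**
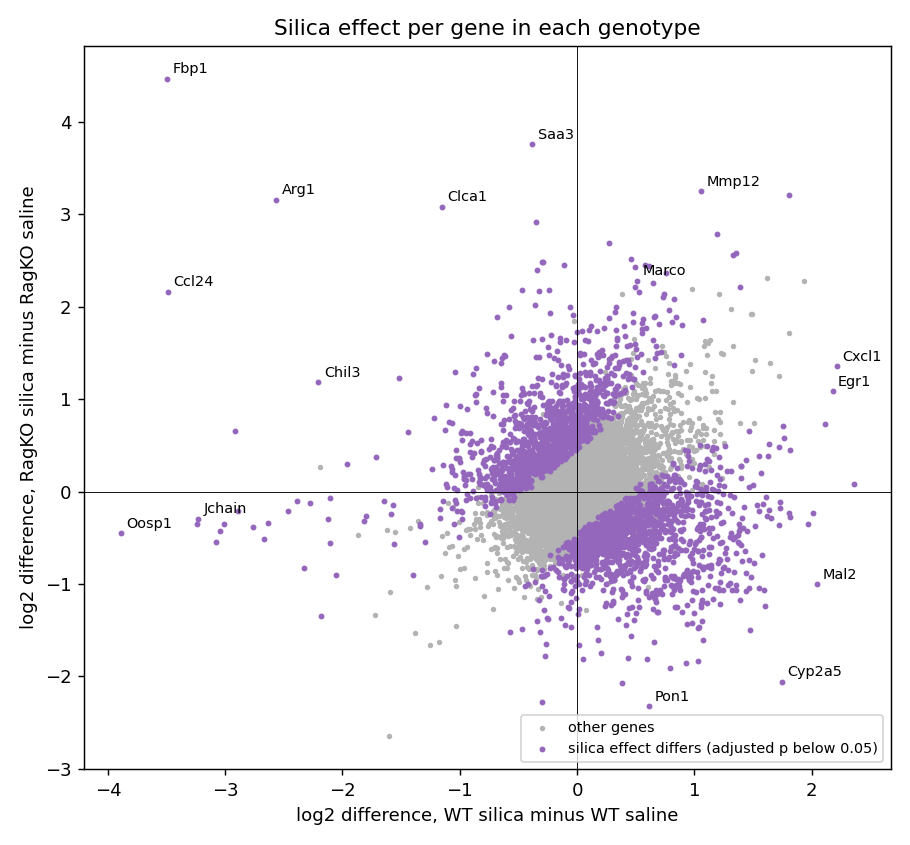
Silica effect on each of 11597 genes as log2 difference in WT (horizontal axis) and in RagKO (vertical axis); purple points are the 2697 genes whose effect differed between the genotypes in limma. The 2 effects correlated across genes with r = 0.0703, and Fbp1, Arg1 and Ccl24 lie at the upper left, lower after silica in WT and higher after silica in RagKO.

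By list, camera with its preset correlation called 25 of 41 as differing between the responses, 20 more positive and 5 more negative in RagKO, with adjusted p from 2.03e-10 to 0.037. No call held with an estimated correlation (5 lists at an unadjusted p below 0.05, and 28 by fry), where the adjusted p was 0.285 for NK cell, fibroblast and interferon-stimulated genes and 0.26 for the other 7 called lists named here. Lung epithelium markers differed in 19 of 21 cases, all more negative (20 over the list alone; Slc34a2 -1.91, Cdh1 -1.73). NK cell markers differed in 9 of 15, all more negative (9 over the list alone; Klrc1 -2.15, Gzma -1.95). Fibroblast markers differed in 11 of 18, 10 negative and 1 positive (11 and 1 over the list alone; Lum -2.13, Myh11 -1.97). More positive were interferon-stimulated genes (19 of 26, or 22 over the list alone; Zbp1 2.50, Isg15 1.73), interferon-gamma response genes (15 of 20 with 2 negative, or 17 and 2 over the list alone; Psmb8 1.68), MHC class II genes (12 of 14, the same over the list alone; Ciita 2.06, H2-Ab1 1.62) and cell cycle genes (19 of 28, or 21 with 1 negative over the list alone; Mki67 2.08). The same held for plasma cell genes (8 of 12, or 9 over the list alone; Derl3 2.89), lysosome genes (11 of 25 with 1 negative, or 18 and 2 over the list alone; Gpnmb 2.57, Lipa 2.25) and alternative macrophage activation genes (14 of 21 with 1 negative, the same over the list alone; Chil4 2.75). For plasma cell genes the silica effect in RagKO had a median of 0.04 and no list call (adjusted p = 0.616 by camera), against -0.96 in WT. Their difference therefore came mainly from the fall in WT. Immediate early genes (adjusted p = 0.29), chemokine ligands (0.18), heat shock genes (0.199) and collagen genes (0.939) were not called by camera. Single members still differed. Of 24 immediate early genes 2 were more positive and 1 more negative, and of 26 chemokine ligands 6 and 3. Of 27 collagen genes 3 were more positive and 4 more negative. Of 15 heat shock genes 6 were more negative, and fry called that list (adjusted p = 0.0472).

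Of the 2283 genes changed by silica in WT and the 3795 changed in RagKO, 1012 were shared. Both responses were upward for 349 (224 for independent lists) and downward for 190 (151), while 332 rose in WT and fell in RagKO (212) and 141 fell in WT and rose in RagKO (160). The same direction was therefore found for 53.3%. Across all genes the responses correlated with r = 0.0703 and Spearman's rho = 0.1051, and r from single pairs of arrays ran from -0.0379 to 0.153; genes are not independent replicates, so no p-value is given. Camera with its preset correlation called 13 lists in both genotypes, and with an estimated correlation it called 0 in either. Of the 13, 9 moved the same way, namely chemokine ligands, immediate early, heat shock, interferon-stimulated, TNF response, classical macrophage activation, complement, collagen and protease genes. The other 4, NK cell markers, epithelium markers, MHC class II and cell cycle genes, moved in opposite directions. Of these 4, fry called only epithelium markers in both genotypes (adjusted p = 0.0123 in WT and 0.0444 in RagKO). Fry did not call MHC class II genes in WT (0.0724), nor NK cell markers (0.056) and cell cycle genes (0.0643) in RagKO. Of the 9, fry did not call interferon-stimulated (0.0927), complement (0.0746) and protease genes (0.114) in WT.

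Averaged over the genotypes in an additive fit, silica changed 1206 genes, 688 up and 518 down, of which 107 rose and 19 fell at least 2-fold. This count fell whenever an array was left out, to 413 and 287 without WT saline replicates 1 and 2, to 453 and 743 without WT silica replicates 1 and 2, to 344 and 421 without RagKO saline replicates 1 and 2, and to 349 and 566 without RagKO silica replicates 1 and 2. It was 713 after quantile normalization, 1880 with array weights, 735 among the more variable genes only, 112 at an adjusted p below 0.01, 2288 below 0.10 and 3559 as a contrast of the 4 group means, where the difference between the responses no longer adds to the spread.

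**Figure D4:**
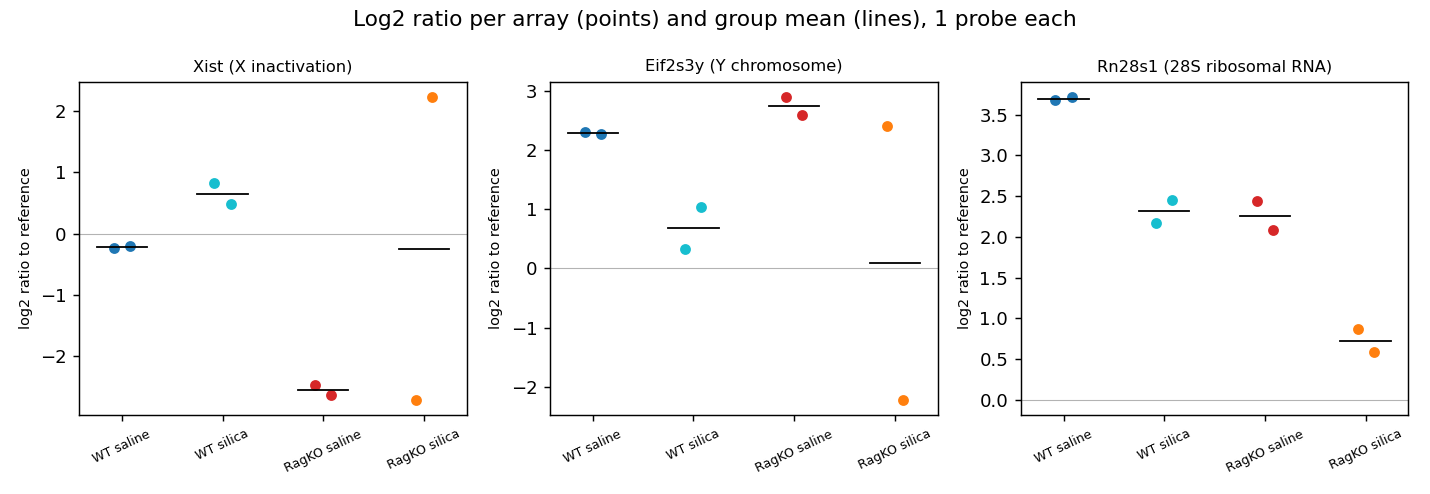
Log2 ratio to the reference RNA of 1 probe each for Xist (the first of 2), Eif2s3y and 28S ribosomal RNA in the 4 groups; points are arrays and lines the means of 2 arrays. RagKO silica replicate 2 stands apart in Xist (2.22) and Eif2s3y (-2.22), and the 28S probe is lower after silica than after saline in both genotypes.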

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

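The tests of exchanged arrays, of sex and of the share of leukocytes were chosen after the results they bear on were seen. The silica effect differed between WT and RagKO for 2697 genes by limma's test of the difference. The same test singled out 8 genes with the largest positive differences, namely Fbp1 (7.96), Arg1 (5.72), Ccl24 (5.65), Clca1 (4.23), Saa3 (4.14), Ccl8 (3.57), Oosp1 (3.44) and Chil3 (3.39). The largest negative differences were in Cyp2a5 (-3.80), Mal2 (-3.05), Maob (-2.98), Pon1 (-2.94), Bex2 (-2.87), Cytl1 (-2.84), Esm1 (-2.78) and Gpx2 (-2.70). These rankings take the WT labels as given. With the WT saline and WT silica arrays exchanged, only Clca1 (1.93), Saa3 (3.38), Pon1 (-1.71), Esm1 (-0.92) and Gpx2 (-1.12) of these 16 would pass in the same direction, Ccl8 (-2.26), Oosp1 (-4.34) and Chil3 (-1.02) would pass in the other, and Fbp1 (0.97, adjusted p = 0.173 by limma), Arg1 (0.60, adjusted p = 0.337) and the other 6 would not pass.

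The difference between the silica effects was also called by camera for 25 lists, with the median log2 difference over each list given here. Positive medians were those of plasma cell genes (1.21), MHC class II genes (1.17), interferon-gamma response genes (1.13), interferon-stimulated genes (1.03), alternative macrophage activation genes (0.89), proteases (0.80), alveolar macrophage markers (0.72), chemokine receptors (0.71) and lysosome genes (0.70). Those of plasmacytoid (0.69) and conventional (0.68) dendritic cell markers, cell cycle genes (0.67), tertiary lymphoid tissue genes (0.67), scavenger receptors (0.65), classical activation genes (0.58), TNF response genes (0.54), group 2 innate lymphoid cell genes (0.51), B cell markers (0.36), neutrophil markers (0.36) and Toll-like receptor genes (0.33) were smaller. For plasma cell genes and B cell markers the silica effect in RagKO was not called (medians 0.04 and -0.21), while both lists fell in WT (medians -0.96 and -0.54). Negative medians were those of lung epithelium (-1.17), NK cell (-0.92), fibroblast (-0.88), mast cell (-0.83) and endothelial markers (-0.34). The adjusted p with an estimated correlation lay between 0.26 and 0.405 for these lists.

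Alternative macrophage activation genes responded more positively to silica in RagKO, where 15 of 21 rose and 1 fell, while in WT 9 fell and 4 rose without a list call (adjusted p = 0.0612 by limma's camera), and Arg1 was lower by -2.56 after silica in WT and higher by 3.16 in RagKO. The sex of the mice behind the arrays was argued against as the whole cause of the rise in RagKO, though by 1 silica array alone. Without RagKO silica replicate 2, the array with high Xist, the list's median rise was 0.83 against 1.12 with it. That array read higher than replicate 1 for Arg1 (5.01 against 3.75), Fbp1 (5.02 against 3.56) and Ccl24 (1.53 against -0.75). Replicate 1 still lay above both RagKO saline arrays for these genes. How much of their rise goes with sex was not tested. The SE of the list's median rise without replicate 2, 0.18, measures the spread between the list's genes and not between arrays. For the fall in WT the sex of the mice stays open as a cause, since Eif2s3y differed by -1.60 between WT silica and WT saline. No arrays of like level exist in both groups. An exchange of the WT saline and WT silica arrays also stays open; it would reverse every WT direction, and 3559 genes would differ between the responses, 7751 between the genotypes after saline and 7283 after silica, in place of 2697, 7680 and 6970. Of 13 lists called in both genotypes 9 moved the same way as labelled, which does not decide it (two-sided binomial test, p = 0.267). The lists also share genes and the same 8 arrays, so they are not independent. The averaged silica effect called 642 genes under the exchange against 1206 as labelled. The 3559 genes are those of the averaged silica effect as a contrast of the 4 group means, which the exchange turns into the difference, so that count is no separate evidence of a differing response. Which genes differ in response and their direction in WT rest on the labels.

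By camera with its preset correlation, epithelial and fibroblast markers were higher in RagKO than in WT after saline, where 9 of 18 endothelial markers were lower and 6 higher without a list call, and all 3 kinds were higher after silica in WT. With an estimated correlation none of these calls held (adjusted p = 0.705 for both lists after saline, and 0.28, 0.273 and 0.273 for epithelial, fibroblast and endothelial markers in WT). A lower share of leukocytes in the RagKO fraction would raise all such markers alike if the mix of structural cells stayed the same. Whether it did was not tested. The medians of epithelial (0.75), fibroblast (1.30) and endothelial markers (-0.32) lay 1.62 apart (permutation p = 0.00963 over 100000 permutations of markers), so a uniform rise was not seen. Pooling the 39 epithelial and fibroblast markers (0.98), a choice made after the medians were seen, put them 1.30 above the 18 endothelial markers (permutation p = 0.00486). The permutations treat markers as independent and leave out the spread between arrays. The estimated correlation was 0.37 for epithelial, 0.30 for fibroblast and 0.11 for endothelial markers. The permutations therefore do not decide whether a lower share of leukocytes contributed. A change in single cell types of that fraction, or in their expression, stays open. In WT after silica the medians of the 3 kinds of marker were all above 0 and lay 0.40 apart (permutation p = 0.0933), so a lower share of leukocytes may contribute there, although Sftpc (-0.82) and Cdh5 (-0.84) fell and Scgb1a1 (0.00) did not pass the test. Of the 57 structural markers 5 are in another list too, the density gradient is meant to enrich leukocytes, and a ratio to a reference gives no share of cells.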

How the results depend on the processing

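No alternative in this part was chosen after the results were seen. Counts of genes between the genotypes stayed within 1.5 times under every alternative run, with 6417 to 7790 after saline and 5736 to 7106 after silica when an array was left out. With median centring the share of these genes higher in RagKO fell from 55.9% to 50.8% after saline. After silica it fell from 56.1% to 51%. Quantile normalization gave 51% after saline and 51.3% after silica. The averaged silica count of 1206 was 713 after quantile normalization, 735 among more variable genes (fewer genes tested), 1880 with array weights, 3559 as a contrast of group means, 112 at an adjusted p below 0.01 and 2288 below 0.10. At 0.01 the counts were 1021 in WT, 1974 in RagKO and 1359 for the difference. Leaving out an array gave 287 to 743 genes for the averaged effect, 861 to 2389 in WT, 2380 to 3842 in RagKO and 1647 to 2485 for the difference; fewer arrays leave fewer degrees of freedom, and a lone array is assumed to vary like the other groups. Camera with an estimated correlation called 0 lists in each of the 5 comparisons (3, 8, 5, 2 and 2 at an unadjusted p below 0.05). Fry called 30 lists for the genotype after saline and 30 after silica, and quantile normalization gave 16 after silica. Where construction does not show it, the cause was not tested. With the replicate number as a block the averaged silica count was 541, and no other count moved by over 1.5 times. The numbers do not pair the arrays, since deviations of same-numbered arrays correlated with r from -0.0728 to 0.1111, and 1 of the pairs of groups passed 0.1. Of 10488 pairs of a named gene result and an alternative, 10279 kept direction and side of the threshold, 186 lost the call, 23 gained it and 0 reversed. Of 1358 such pairs for called lists, 143 lost the call and 0 were called in the other direction. Signal over background was not given, so its effect on precision is unknown.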

Other observations

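Several lists that were not called held genes that moved strongly. Inflammasome and interleukin-1 genes were not called after silica in WT (6 of 20 rose, 1 fell; adjusted p = 0.366) or in RagKO (7 rose, 2 fell; adjusted p = 0.0982), yet Il1a rose by 2.26 in RagKO, and Il18r1 rose by 0.88 in WT and changed by -1.06 in RagKO, a difference of -1.94. Oxidative stress genes in RagKO went both ways (7 of 24 rose and 6 fell; adjusted p = 0.481), with Gsta1 at -1.78 and Sod2 at 0.99. Neutrophil markers in RagKO also went both ways (5 of 16 rose and 7 fell; adjusted p = 0.372), with Lcn2 at 1.63 and Stfa2l1 at -1.34; Stfa genes share sequence, so that value is uncertain. Lipid handling genes in RagKO (10 of 22 rose and 3 fell; adjusted p = 0.07) included Ch25h, an enzyme that oxidises cholesterol, at 2.18. Monocyte markers (6 of 17 rose and 3 fell in RagKO; adjusted p = 0.0565) included Nr4a1, which rose by 1.13 in WT and 1.64 in RagKO. Ribosomal protein genes were not called in WT (adjusted p = 0.159) or RagKO (adjusted p = 0.831).

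Neither averaged effect was matched by another split of the 8 arrays into 4 and 4, with the other factor in the fit, and these tests were planned. For silica 1 of 34 splits, the real split, called as many genes, with 1206 against 642 for the highest other. For genotype 1 of 34 splits did so, with 7353 against 4. All splits that part the arrays of a group called 0 genes, since they put the differences between groups into the spread, and only 1 other split per factor kept the arrays of each group together, so these counts say little about chance.

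A further hypothesis, also planned, was that DNA of another mouse strain next to Rag1 could contribute to large genotype differences outside the lymphocyte lists. The median absolute genotype difference, averaged over exposures, of the 20 genes around Rag1 was 0.43, against a median of 0.45 over 11153 windows of 20 neighbouring genes, and 55.9% of windows were as large. The neighbours as a set therefore did not differ more than genes elsewhere. A median over 20 genes cannot show a flank that alters only some neighbours or affects genes elsewhere, so the hypothesis was not decided. The neighbour Iftap differed by 2.14 (limma, adjusted p = 0.000113), which leaves single neighbours open.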
